A study of Mus musculus with 4 samples.

How the data were processed

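Ribosome-bound RNA was sequenced from the deep cerebellar nuclei of Slc17a6-TRAP mice (line JX883) in 4 immunopurified libraries, each from 3 mice. Tissue was homogenised, tagged polysomes were captured on magnetic beads with monoclonal anti-EGFP antibodies, and the RNA was purified with a kit for small amounts, per the labels' protocols. Each deposited file holds whole-number counts per gene name for 1 library, with 5 summary rows of the counting program. STAR 2.0.0e, HTSeq and the build mm10 are named in the submitters' processing notes. The annotation, the strandedness of the counting and the library kit are not given in the sources used here, so reads of a gene and of an antisense gene over the same exons may not be separated. Of the 245 named genes, 72 overlap exons of a gene on the opposite strand. Amplification before sequencing is not corrected by molecular identifiers in these counts, so floors and counting intervals cover counting error only.

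The files list 32532 gene names. The summary rows were kept out of library sizes and tests. Reads with no feature made up 14.1, 19.5, 21.1 and 19.3% of all counted reads in replicates 1 to 4, reads that were not unique 14.2, 19.0, 20.6 and 18.8%, and ambiguous reads 2.94, 2.07, 2.04 and 2.20%. A count was seen for 16343, 16749, 15492 and 14952 genes. All pairs of libraries differed by more than sampling noise (chi-square per degree of freedom from 34.9 to 127), so no library is a copy of another. This does not show that the pools of mice were separate, which the labels do not say. No mitochondrially encoded gene was among the names, so that list had 0 measured members. Hba-a1 and Hbb-bt were not measured, and Scn2a was read under its older symbol Scn2a1.

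Levels were planned as counts divided by exon length, with CPM to replace them if fewer than 80% of names had a length. GENCODE release 21 for mouse, on the same build as mm10, gave a length to 73.6% of names (23155 by symbol and 773 through an older symbol), so CPM over all named genes is the main level. Among genes with at least 10 counts in every library 97.2% had a length, and levels per union exon length, scaled to 1000000, were added as an alternative. Coordinates come from that annotation. Rn45s stayed in the library totals, and totals without it were an added alternative.

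Gene pairs were compared with the moderated test of limma 3.58.1, with Benjamini-Hochberg adjustment over 48 pairs and a threshold of 0.05, two-sided. Moderation draws the variance of each pair toward a common value estimated over all pairs. The value tested was the mean over libraries of the difference in log2(CPM + 0.5). Ratios, and the folds they give, are on that scale, which understates the ratios of low genes. The 14 cell type lists were set against the glutamatergic nuclear neuron markers in the same way, on the mean over members, with genes shared by both lists left out. Each library was set against the other 3 with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit with robust estimation, glmQLFTest), which leaves 2 residual degrees of freedom. The standard error of a fold change was taken from the fold change and its F statistic. Gene lists with at least 5 tested members, 31 in all, were tested with limma's camera (preset correlation 0.01, prior count 2), with an estimated correlation and fry as checks. Of the list tests, that of replicate 4 was planned, and those of replicates 1 to 3 were added after the data had been seen. Members of each called list were then tested over that list alone, in the same comparison that had called it. Calls on such members are therefore no separate support for their list. A library was also called far from the others by Dixon's ratio, with a critical value of 0.829 for 4 samples.

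The 36 gene lists and 48 pairs, and the rule for the genes named, were fixed before the data were examined. Named are the genes of the pairs, the 5 highest members and the lowest member of each list, the 10 most abundant genes, and the 10 genes of largest tagwise dispersion among those with at least 10 CPM. Up to 10 genes in each direction with the largest log2 fold change past the threshold in each test of 1 library with a mean of at least 10 CPM, and Rpl10a, complete the rule. Ankrd63 and Gm20110, called at a lower mean level, and genes named for a call over a list alone, for the weighing of explanations or as family members fall outside the rule and were chosen after their values were seen. The genes of largest dispersion included Tcf7l2, Trim25, Gabrd, Hspg2, Tox3, Nps, Usb1 and Gm340. Some genes that the rule names are not reported here, and counts of pairs, lists and genes still include them.

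Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, a fold minimum, other pseudocounts, the longest transcript as length, the trend with its length (lowess) taken out of each library for the list tests, list medians, a reference list without Slc17a6, exact sign-flip tests and leaving out each library in turn. The methods were tested on simulated counts for 11227 genes with the libraries' means and sizes. Genes were drawn independently with the same relative level in every library, and changes were put only into genes of at least 10 CPM. The real tests covered 15083 genes, and the real libraries also differed along transcript length. The shares recovered may therefore be too high for the real libraries. For each library against the other 3, 100% of genes made 16- or 64-fold higher were recovered. Of genes made 4-fold higher, 76, 56, 72 and 50% were recovered for replicates 1 to 4, and of those made 16-fold lower, 80, 74, 78 and 80%. False calls numbered 10, 6, 10 and 3. In 48 simulated pairs, 2.02% of unchanged and 100% of 4-fold pairs were called. In 35 simulated lists, the 1 shifted list was called and 0 of the 34 others.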

Results

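Ribosome-bound RNA was profiled from the deep cerebellar nuclei, the output nuclei of the cerebellum, of mice of the Slc17a6-TRAP line JX883. In translating ribosome affinity purification (TRAP), a chosen cell type carries an EGFP-tagged ribosomal protein, and the RNA bound to tagged ribosomes is pulled down with antibodies against EGFP. The line is named for Slc17a6, which encodes a vesicular glutamate transporter and marks glutamatergic neurons. The samples form 1 group of 4 immunopurified libraries, each from 3 mice. Replicates 1, 2 and 3 carry the library numbers 1300, 1301 and 1302, and replicate 4 carries 1476. The labels do not say more of how the mice were divided, so p-values concern the spread between these 4 libraries. In limma's test that spread is moderated, with the variance of each pair or list drawn toward a value common to all of them. The SD printed beside a ratio is not moderated, so a ratio with a wide SD may pass through the common value. No input RNA, second cell type or treatment was among the samples used here, so enrichment over the tissue was not measured. The results are therefore levels, ratios between genes within a library, and differences of 1 library from the other 3. Counts assigned to genes totalled 9621762, 10306407, 10436291 and 10988373 in replicates 1 to 4. A gene with no count in a library may still be present at up to 0.312, 0.291, 0.287 and 0.273 counts per 1000000 (CPM) in replicates 1 to 4, the level of 3 counts. These limits cover counting error only. Values are mean CPM ± SD over the 4 libraries unless stated, and CPM is not divided by gene length. Coordinates are on mm10.

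Slc17a6 stood at 2143 ± 153 CPM (SD, n = 4), and its 4 libraries ranged from 2011 to 2309 CPM. The gene lies on chromosome 7 at 51622006 to 51671119, on the plus strand. The other vesicular glutamate transporters were far lower, with Slc17a7 at 49.0 ± 23.9 CPM and Slc17a8 at 1.35 ± 1.36 CPM. Within a library, Slc17a6 exceeded Slc17a7 by a log2 ratio of 5.57 ± 0.80 (limma, adjusted p = 5.0e-07) and Slc17a8 by 10.56 ± 1.27 (adjusted p = 4.7e-08), each in 4 of 4 libraries. Slc17a8 had no count in replicate 3, so the size of its ratio depends on the pseudocount. Slc38a1, a neuronal amino acid transporter, stood at 594 ± 47.8 CPM. Rpl10a, the gene of the ribosomal protein that carries the tag, stood at 164 ± 36.9 CPM.

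Genes of GABA and glycine transmission were detected below Slc17a6. Gad2 and Gad1, the GABA-synthesising enzymes, stood at 120 ± 82.4 and 45.6 ± 32.7 CPM. Slc32a1, the vesicular transporter of both transmitters, stood at 12.4 ± 12.4 CPM, and Slc6a5, the glycine transporter of glycinergic neurons, at 3.37 ± 4.42 CPM. Slc17a6 exceeded Gad2 by a log2 ratio of 4.37 ± 1.0 (adjusted p = 4.4e-06), Gad1 by 5.83 ± 1.19 (adjusted p = 1.0e-06), Slc32a1 by 8.04 ± 1.88 (adjusted p = 7.2e-07) and Slc6a5 by 9.87 ± 1.87 (limma, adjusted p = 2.1e-07). Each held in 4 of 4 libraries. Gad2 was above Gad1, with a Gad1 to Gad2 log2 ratio of -1.46 ± 0.38 (limma, adjusted p = 0.0032), and Slc32a1 was above Slc6a5 by 1.82 ± 0.54 (adjusted p = 0.0010). Slc6a5 had no count in replicate 4, so its ratios depend on the pseudocount. Slc6a9, a glycine transporter gene, stood at 13.3 ± 3.03 CPM.

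**Figure D1:**
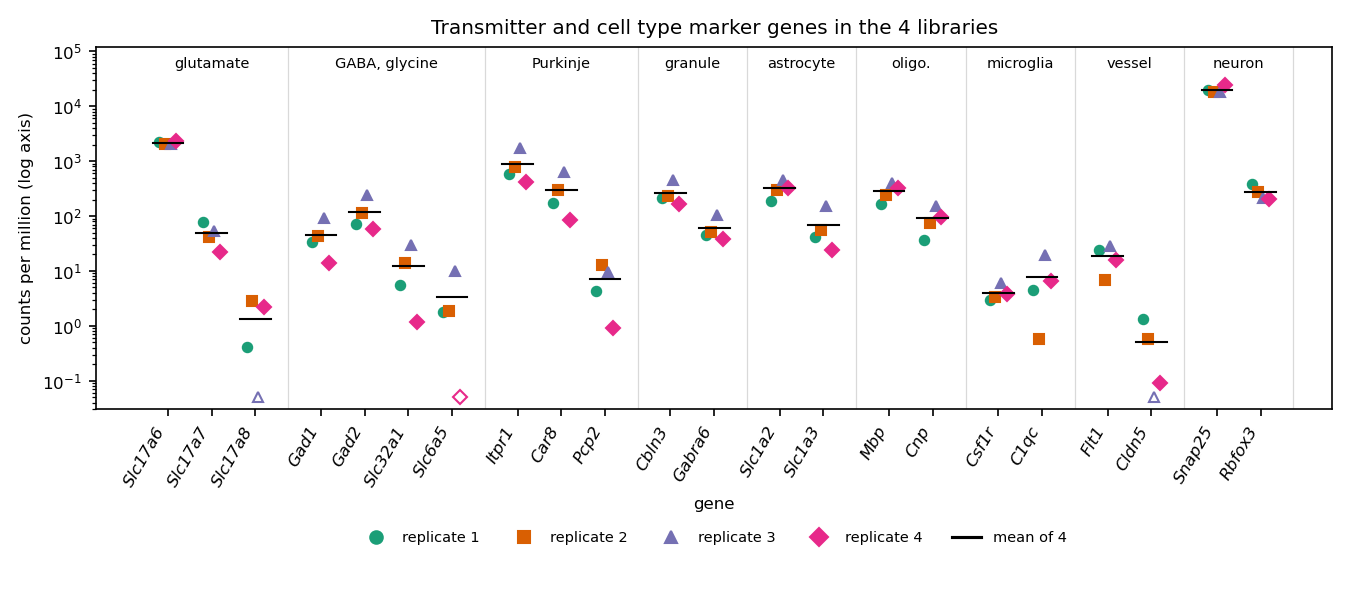
CPM on a log axis for transmitter and cell type marker genes, with 1 point per library and a line at the mean of 4; open symbols at the bottom mark a count of 0. Slc17a6 lies between 2011 and 2309 CPM in the 4 libraries, whereas Gad1, Gad2 and Slc32a1 spread widely and are highest in replicate 3.

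In all, 11213 genes reached 1 CPM in all 4 libraries. The most abundant name was Rn45s, the ribosomal RNA precursor, at 94352 ± 51732 CPM, which took 4.99, 14.2, 13.6 and 4.92% of the counts in replicates 1 to 4. Next came Snap25, a protein of synaptic vesicle fusion, at 20122 ± 3009 CPM (chromosome 2, 136713453 to 136782428). Lars2, a mitochondrial leucine-tRNA synthetase, stood at 6441 ± 2506 CPM. Like Rn45s, Lars2 was higher in replicates 2 and 3 (9594 and 7277 CPM) than in replicates 1 and 4 (4100 and 4794 CPM). Whether its reads are independent of ribosomal RNA was not tested. Also among the 10 most abundant were Map1b at 5069 ± 1926, Vsnl1 at 4779 ± 2085, Atp1b1 at 3770 ± 390, Gnas at 3353 ± 238 and Ywhaz at 3299 ± 882 CPM. Among the 10 genes fixed as pan-neuronal, all 10 reached 1 CPM in every library. After Snap25 these were led by Syn1 at 992 ± 698, Thy1 at 750 ± 114, Eno2 at 680 ± 190 and Map2 at 667 ± 233 CPM, and the lowest was Tubb3 at 105 ± 43.3 CPM.

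Pairs of related genes were compared within each library to ask which member was more abundant in the ribosome-bound RNA. Of 48 pairs fixed before the data were examined, 38 passed the threshold (limma, adjusted p under 0.05), 32 with the first gene higher and 6 with the second. With values divided by exon length, 37 pairs passed, and 33 of the 38 kept their call and direction. An exact sign-flip test over 4 libraries cannot pass the threshold, its smallest adjusted p for a called pair being 0.146, as for ratio Slc17a6/Slc17a7, so it called 0 pairs.

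All 15 GABA receptor genes of the list reached 1 CPM in every library. Gabbr1 stood at 498 ± 85.1, Gabrb2 at 309 ± 93.3 and Gabbr2 at 201 ± 13.2 CPM, and Gabrb1 was lowest at 9.02 ± 3.89 CPM. Of the glycine receptor genes, the beta subunit Glrb stood at 322 ± 62.2 CPM. Glra1, at 64.6 ± 25.9 CPM, exceeded Glra3 by a log2 ratio of 2.88 ± 0.70 (limma, adjusted p = 5.2e-05) and Glra2 by 1.32 ± 0.78 (adjusted p = 0.0115). The call on the ratio Glra1/Glra2 was lost without replicate 2 (log2 ratio 1.13, adjusted p = 0.0747).

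Of 18 ionotropic glutamate receptor genes, 17 reached 1 CPM in every library. Gria2 at 303 ± 104, Gria3 at 267 ± 106, Grin1 at 209 ± 17.4, Gria4 at 175 ± 25.3 and Grik3 at 111 ± 35.1 CPM were the highest, and Grin3b at 1.01 ± 0.83 CPM was the lowest. Gria4 exceeded Gria1 by a log2 ratio of 1.22 ± 0.59 (limma, adjusted p = 0.0121). Gria2 exceeded Gria1 by 1.95 ± 0.64 (adjusted p = 8.4e-04), but per exon length the ratio was 0.59 (adjusted p = 0.164). Grin2b exceeded Grin2a, with a ratio Grin2a/Grin2b of -1.10 ± 0.53 (limma, adjusted p = 0.0175). Per exon length that ratio was -0.60 (adjusted p = 0.146), without replicate 2 it was -0.84 (adjusted p = 0.126) and without replicate 1 it was -1.14 (adjusted p = 0.0502). Grin2a and Grin2c differed by 0.33 ± 1.09 (adjusted p = 0.524), yet per exon length Grin2c was higher (ratio -1.39, adjusted p = 0.0153). Grin2a and Grin2d, at 16.6 ± 7.68 and 20.3 ± 14.4 CPM, differed by -0.04 ± 0.96 (adjusted p = 0.961), and per exon length by -1.38 (limma, adjusted p = 0.0136). Gria2 and Gria4 did not pass the threshold, with a log2 ratio of 0.73 ± 0.59 (adjusted p = 0.0888), and per exon length the sign turned (-0.56, adjusted p = 0.171). Of the 8 metabotropic receptors, Grm5 stood at 136 ± 22.6 and Grm4 at 116 ± 18.2 CPM. Grm7 and Grm3 stood at 21.2 ± 9.10 and 19.4 ± 9.14 CPM, and Grm6 had no count in any library.

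Of 39 receptor genes for monoamines and acetylcholine, 21 reached 1 CPM in all libraries. Chrna4, a nicotinic receptor subunit, led at 158 ± 53.7 CPM, then Htr2c at 117 ± 29.0, Chrnb2 at 77.4 ± 7.57, the histamine receptor gene Hrh3 at 74.7 ± 4.70 and Htr5a at 64.2 ± 18.0 CPM. Htr2c exceeded Htr2a, at 3.14 ± 2.19 CPM, with an Htr2a to Htr2c log2 ratio of -5.24 ± 1.30 (limma, adjusted p = 3.5e-06). Chrm2 and Chrm3 stood at 19.7 ± 8.61 and 19.6 ± 7.82 CPM, a ratio of 0.01 ± 0.62 (adjusted p = 0.970). Drd4 and Adra2b had no count in any library.

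Of the potassium channel genes, Kcna2 stood at 812 ± 177, Kcna1 at 449 ± 102 and Kcnc1 at 392 ± 20.2 CPM, and the lowest of 16 was Kcna4 at 7.66 ± 5.14 CPM. Kcnc1, a channel subunit of fast-spiking neurons, exceeded Kcnc2 by a log2 ratio of 1.84 ± 0.41 (limma, adjusted p = 8.2e-04). Kcna2 exceeded Kcna1, with a ratio Kcna1/Kcna2 of -0.86 ± 0.26 (limma, adjusted p = 0.0399). That call ended when any 1 library was left out (adjusted p from 0.0508 to 0.132), and per exon length the sign turned (0.46, adjusted p = 0.218). Of the calcium-activated channels, Kcnma1 stood at 147 ± 37.9, Kcnn3 at 20.1 ± 7.40, Kcnn2 at 13.6 ± 2.50 and Kcnn1 at 3.12 ± 2.51 CPM, and Kcnn4 had no count in any library. Kcnn2 exceeded Kcnn1 by 2.38 ± 1.72 (moderated SE 0.58, limma adjusted p = 0.0032), and the ratio ranged from 0.84 in replicate 1 to 4.83 in replicate 4.

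Scn8a at 892 ± 138 and Scn1a at 609 ± 63.0 CPM were the most abundant sodium channel genes. They exceeded Scn2a, listed under its older symbol Scn2a1 at 211 ± 21.1 CPM, by log2 ratios of 2.07 ± 0.27 (limma, adjusted p = 2.8e-04) and 1.53 ± 0.21 (adjusted p = 0.0020). The beta subunit genes Scn2b and Scn4b stood at 306 ± 47.7 and 143 ± 40.1 CPM, a ratio Scn4b/Scn2b of -1.13 ± 0.45 (limma, adjusted p = 0.0138). That call was lost without replicate 2 (adjusted p = 0.0671) and without replicate 4 (adjusted p = 0.0517). Scn9a was the lowest of the 10 sodium channel genes at 19.0 ± 4.27 CPM. Of the calcium channel genes, Cacna1e stood at 209 ± 67.1, Cacna1a at 175 ± 28.9, Cacna1b at 92.9 ± 38.1, Cacna1c at 84.7 ± 20.1 and the T-type gene Cacna1g at 65.1 ± 22.5 CPM. Cacna1g exceeded Cacna1h, the lowest of 8 at 15.4 ± 5.58 CPM, by 2.04 ± 0.82 (adjusted p = 9.4e-04) and was not told apart from Cacna1i (0.25 ± 0.20, adjusted p = 0.524). Cacna1a exceeded Cacna1b by 1.0 ± 0.82 (adjusted p = 0.0399). The call on the ratio Cacna1a/Cacna1b was lost per exon length (0.80, adjusted p = 0.0916) and without replicate 3 (0.61, adjusted p = 0.210), replicate 2 (adjusted p = 0.111) or replicate 1 (adjusted p = 0.0510). Of the channels of the hyperpolarisation-activated current, Hcn4 stood at 32.5 ± 8.71, Hcn3 at 28.0 ± 13.7 and Hcn2 at 26.9 ± 11.8 CPM.

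Neurofilament genes were among the abundant structural genes, with Nefm at 1351 ± 771, Nefl at 1270 ± 320 and Nefh at 250 ± 79.2 CPM. Nefm and Nefl overlap on opposite strands, so their counts are uncertain if the counting ignored strand. The calcium-binding protein gene Pvalb, at 129 ± 56.9 CPM, exceeded Calb1 by a log2 ratio of 1.57 ± 0.66 (limma, adjusted p = 0.0032). Pvalb and Calb2 did not pass (1.0 ± 1.29, adjusted p = 0.0789), although the ratio Pvalb/Calb2 did per exon length (1.75, adjusted p = 0.00828) and without replicate 4 (1.41, adjusted p = 0.00468). Slc12a5, the chloride extruder of mature neurons, stood at 445 ± 20.2 CPM and exceeded Slc12a2 by 3.54 ± 0.78 (adjusted p = 1.3e-05). Syt1 exceeded Syt2, with a Syt2 to Syt1 ratio of -1.93 ± 1.11 (limma, adjusted p = 0.0028). Vamp1 and Vamp2, at 1056 ± 146 and 1874 ± 563 CPM, differed by -0.79 ± 0.35 (adjusted p = 0.0557), and per exon length by -2.21 (adjusted p = 2.1e-04).

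Transcription factors used as markers of glutamatergic nuclear neurons covered a wide range. Meis2 stood at 342 ± 91.2 and Lhx9 at 91.6 ± 53.8 CPM, whereas Tbr1 stood at 7.74 ± 5.79 and Irx3, the lowest of the 11 markers, at 6.10 ± 4.28 CPM. Meis2 exceeded Meis1 by a log2 ratio of 2.94 ± 0.46 (limma, adjusted p = 2.3e-05). Lhx9 exceeded Lhx2 by 1.27 ± 1.10 (adjusted p = 0.0245). The call on the ratio Lhx9/Lhx2 was lost per exon length (0.17, adjusted p = 0.735), without replicate 4 (0.78, adjusted p = 0.121) and without replicate 1 (adjusted p = 0.0909). Tbr1 and Eomes were not told apart (-0.29 ± 0.87, adjusted p = 0.524). Spp1, another marker of these neurons, stood at 102 ± 41.2 CPM.

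**Figure D2:**
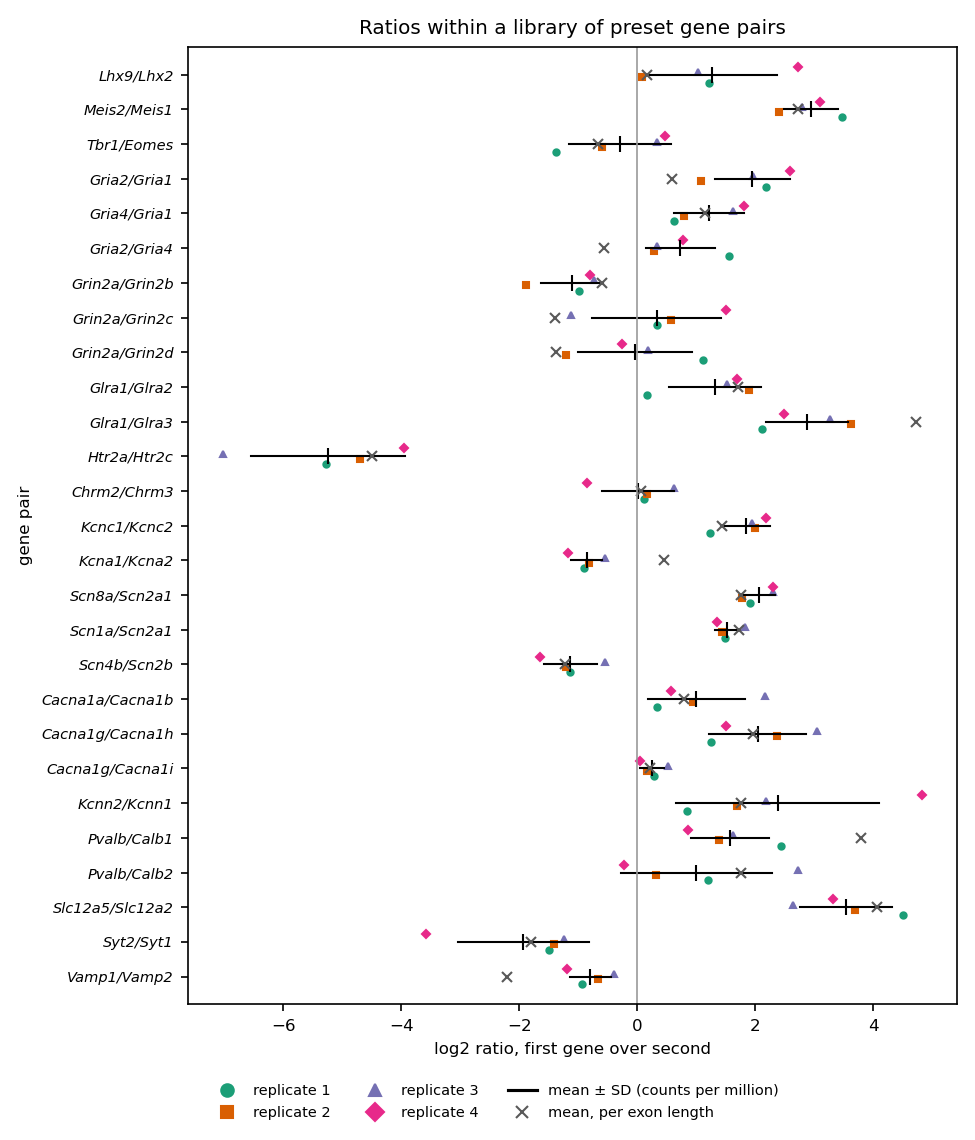
Log2 ratios of 27 of the preset gene pairs, with 1 coloured point per library, a black mark and line for the mean ± SD of 4 libraries in CPM, and a grey cross for the mean per exon length. The Meis2 to Meis1 ratio lies at 2.94 and the Htr2a to Htr2c ratio at -5.24, and crosses on the other side of 0 from the black mark include Kcna1 to Kcna2.

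Of 23 neuropeptide genes, 9 reached 1 CPM in all libraries. Sst, which encodes somatostatin, stood at 836 ± 362 CPM, Scg2 at 468 ± 172, Penk, the enkephalin precursor, at 361 ± 145, Cck at 200 ± 205 and Nxph1 at 76.6 ± 25.2 CPM. Perineuronal net genes were led by the link protein gene Hapln4 at 324 ± 70.5 CPM, with Ncan at 58.0 ± 25.1, Tnr at 36.6 ± 11.9, Bcan at 29.6 ± 10.4 and Vcan at 19.3 ± 11.7 CPM, and Hapln3 had no count in any library. Of 27 hereditary ataxia genes, 26 reached 1 CPM in every library, among them Itpr1 at 886 ± 589, Ttbk2 at 683 ± 88.6, Atxn2 at 324 ± 112 and Atxn1 at 254 ± 25.4 CPM. Immediate early genes, which neuronal activity induces, were led by Egr1 at 189 ± 97.3, Dusp1 at 68.7 ± 9.90, Arc at 25.6 ± 9.71, Fosb at 11.3 ± 7.31 and Fos at 9.99 ± 8.29 CPM, and Egr2 was lowest at 0.414 ± 0.765 CPM. Among RNAs known to be retained in the nucleus, Malat1 stood at 2525 ± 741, Meg3 at 329 ± 30.2, Snhg11 at 129 ± 14.9 and Neat1 at 7.78 ± 7.31 CPM. Monoamine and acetylcholine transmitter genes were low. Slc18a2 stood at 16.1 ± 11.6, Th at 15.7 ± 13.6, Slc5a7 at 14.9 ± 15.6, Slc6a2 at 7.79 ± 6.75 and Dbh at 6.86 ± 8.78 CPM, and Tph2 was lowest at 0.05 ± 0.10 CPM.

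To set the markers of other cell types beside those of the targeted neurons, the mean log2 level of each list was compared with that of the glutamatergic nuclear neuron markers in the same library. Of 14 lists, 10 were lower, 2 were higher and 2 did not pass the threshold (limma, adjusted p under 0.05). The lists use different genes, so these differences do not give the share of any cell type. Microglia markers lay lower by a log2 difference of -4.79 ± 0.51, endothelial and pericyte markers by -3.91 ± 0.65, choroid plexus and ependyma markers by -4.78 ± 1.06, blood cell genes by -5.20 ± 0.71 and caudal hindbrain Hox genes by -6.11 ± 0.30 (adjusted p from 1.7e-08 to 9.0e-07). Inhibitory nuclear neuron markers lay lower by -2.80 ± 1.11 (adjusted p = 8.4e-05) and oligodendrocyte precursor markers by -2.76 ± 0.75 (limma, adjusted p = 2.1e-05). Astrocyte and Bergmann glia markers lay lower by -1.56 ± 0.71 (adjusted p = 0.0012). The molecular layer interneuron and Golgi cell markers lay lower by -1.21 ± 0.29 (adjusted p = 0.0017), a call lost for the level of molecular layer interneuron and Golgi cell markers against the reference list with medians in place of means (adjusted p = 0.158). For unipolar brush cell markers the difference was -0.83 ± 0.43 (adjusted p = 0.0194). The call on the level of unipolar brush cell markers against the reference list was lost without Slc17a6 in that list (-0.23, adjusted p = 0.47), without replicate 1 (adjusted p = 0.118) and without replicate 2 (adjusted p = 0.0690). Pan-neuronal genes lay higher by 3.55 ± 0.14 (adjusted p = 4.6e-07).

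Granule cell markers were higher than the reference by a log2 difference of 0.80 ± 0.67 (limma, adjusted p = 0.0365). The call on the level of granule cell markers against the reference list was lost per exon length (0.55, adjusted p = 0.154), with list medians (0.67, adjusted p = 0.239), without replicate 3 (0.48, adjusted p = 0.114) and without replicate 2 (adjusted p = 0.0844). Their leading genes were Cbln3 at 264 ± 123, Chn2 at 155 ± 49.8, Fat2 at 137 ± 87.4 and Etv1 at 85.1 ± 25.1 CPM. Gabra6, a GABA receptor subunit of granule cells, stood 5.26 ± 0.72 below Slc17a6 on the log2 scale (adjusted p = 5.8e-07). Purkinje cell markers did not pass (-0.05 ± 0.77, adjusted p = 0.886), with Itpr1 at 886 ± 589, Rgs8 at 607 ± 147, Aldoc at 299 ± 102 and Car8 at 293 ± 235 CPM. Pcp2, a Purkinje cell gene, stood at 6.99 ± 5.39 CPM and 8.59 ± 1.55 below Slc17a6 on the log2 scale (limma, adjusted p = 2.1e-07). Pet100 overlaps Pcp2 on the opposite strand. Oligodendrocyte markers did not pass (-0.66 ± 0.73, adjusted p = 0.0781). The level of oligodendrocyte markers against the reference list did so without replicate 3 (-0.91, adjusted p = 0.0399) and without replicate 4 (-0.82, adjusted p = 0.0387). Mbp, a gene of myelin, stood at 286 ± 103 CPM, and Snap25 exceeded Mbp by 6.20 ± 0.59 and Slc1a3 by 8.52 ± 1.28 (adjusted p = 2.1e-07 and 2.0e-07). The astrocyte genes Slc1a2, Slc1a3 and Aqp4 stood at 319 ± 110, 67.9 ± 56.6 and 54.7 ± 9.12 CPM.

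**Figure D3:**
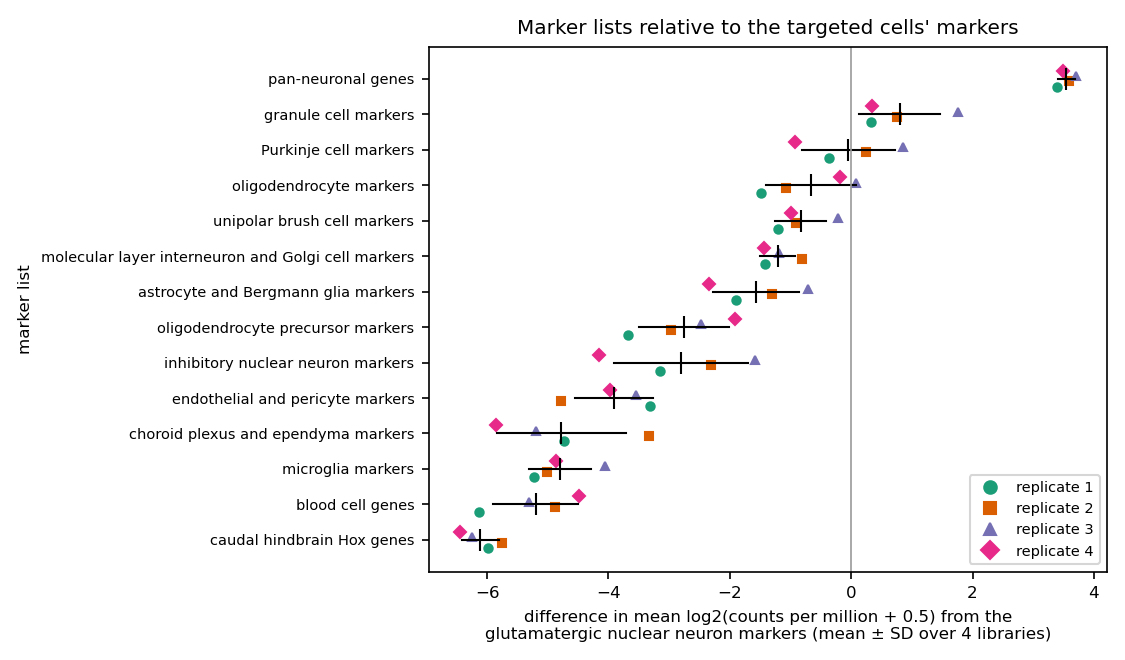
Difference in mean log2(CPM + 0.5) between each marker list and the glutamatergic nuclear neuron markers, with 1 point per library and a black mark and line for the mean ± SD of 4 libraries. Pan-neuronal genes lie at 3.55 and caudal hindbrain Hox genes at -6.11, and granule and Purkinje cell markers are highest in replicate 3.

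The libraries differed from each other, and each was set against the other 3 with edgeR's quasi-likelihood test over 15083 genes. This compares libraries, not conditions, and assumes that the lone library varies like the other 3. By chance, 5% of genes would have an unadjusted p under 0.05. Replicates 1 and 2 lay below that share, and replicates 3 and 4 lay above it. Few calls in replicates 1 and 2 therefore do not show that they were like the others. Pairwise correlations across genes of log2 levels ranged from 0.857 for replicates 3 and 4 to 0.932 for replicates 1 and 2. The common biological coefficient of variation was 0.414.

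In replicate 1, 3 genes were higher and 0 lower, with 497 of 15083 genes at an unadjusted p under 0.05. Tcf7l2, a transcription factor of Wnt signalling (chromosome 19, 55741820 to 55933654), stood at 2486 CPM against 22.8, 42.0 and 8.55 CPM in replicates 2 to 4 (log2 fold change 6.48, SE 0.58, edgeR adjusted p = 5.6e-04). Its pooled counts give a ratio of 103 (95% exact binomial interval 95.7 to 111). This interval, and those of Tfap2d and Ankrd63 below, cover counting error only and not the spread between libraries. Tfap2d, a transcription factor gene (chromosome 1, 19103022 to 19166346), stood at 146 CPM against 1.07, 0.19 and 0 CPM (edgeR adjusted p = 0.0023), a pooled ratio of 357 (interval 208 to 673). DESeq2 did not call the change of Tfap2d in replicate 1 (adjusted p = 0.365). Ankrd63 had 306 counts in replicate 1 and 1 count in the other 3 together, a ratio of 1009 (interval 180 to 39988, edgeR adjusted p = 0.0311). The number of genes called was 32 with no filter on low counts, 26 with DESeq2, and 7, 17 and 31 without replicates 2, 3 and 4.

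Among 4 gene lists called in replicate 1, each lost its call with an estimated correlation (adjusted p = 0.782) and with fry. Oligodendrocyte markers were lower (10 of 10 members, median log2 change -1.27, camera adjusted p = 9.7e-04), as were oligodendrocyte precursor markers (6 of 6, -1.48, adjusted p = 0.0089) and nuclear-retained RNAs (7 of 7, -0.86, adjusted p = 0.0328). Of the lists of other cell types, none of which passed, endothelial and pericyte markers (7 of 10, 0.85, adjusted p = 0.0803) and choroid plexus and ependyma markers (3 of 5, 0.84, adjusted p = 0.946) had medians above 0. Medians were lower for granule cells (7 of 8, -0.71, adjusted p = 0.0729), astrocytes (7 of 10, -0.57, adjusted p = 0.0957), microglia (6 of 7, -0.61, adjusted p = 0.187) and Purkinje cells (9 of 10, -0.51, adjusted p = 0.187), among others. Immediate early genes were higher (9 of 10 members, median 1.39, adjusted p = 0.0136), with Egr1 at 326 CPM against 94.8 to 170 CPM in the others. Changes in this library also ran with transcript length (Spearman's rho -0.27 across genes), and its ribosomal protein genes summed to 10438 CPM against 4255 to 6832 CPM in the others. With the length trend removed, a setting added after the data were seen, the call on nuclear-retained RNAs in replicate 1 was lost (-0.40, adjusted p = 0.261). Those on oligodendrocyte markers in replicate 1 (-1.22, adjusted p = 5.9e-04), oligodendrocyte precursor markers in replicate 1 (-1.37, adjusted p = 0.00608) and immediate early genes in replicate 1 (1.20, adjusted p = 0.0132) stayed. Over the list alone, edgeR called 2 of the 10 oligodendrocyte genes, Cnp among them, and 0 of the members of the other 3 lists, of which 0 precursor genes, 1 early gene and 1 nuclear-retained RNA had an unadjusted p under 0.05. The call on oligodendrocyte precursor markers in replicate 1 was lost without replicate 4 (adjusted p = 0.0594) and that on nuclear-retained RNAs in replicate 1 without replicate 3 (adjusted p = 0.0838).

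In replicate 2, edgeR called 0 genes, with 78 genes at an unadjusted p under 0.05. DESeq2 called 7, and leaving out replicates 1, 3 and 4 gave 0, 1 and 2. Each of 4 lists called lost its call with an estimated correlation (adjusted p = 0.907) and with fry. Genes of monoamine and acetylcholine transmission were higher as a list (9 of 10 members, median log2 change 2.11, camera adjusted p = 0.0039), with Slc5a7, the choline transporter gene, at 35.8 CPM against 2.18 to 17.7 CPM in the others. Choroid plexus and ependyma markers were higher (5 of 5, 3.47, adjusted p = 0.00265). Their leading gene Ttr, the transthyretin gene, stood at 190 CPM against 44.9, 4.5 and 0 CPM in replicates 1, 3 and 4. Neuropeptides were higher by members (13 of 20, 0.69, adjusted p = 0.00265) but not in sum, at 1627 CPM against 2927, 1280 and 2511 CPM in replicates 1, 3 and 4. Endothelial and pericyte markers were lower (9 of 10, -1.48, adjusted p = 2.9e-06). Without replicate 3 the calls on monoamine and acetylcholine transmitter genes in replicate 2 and on neuropeptides in replicate 2 were lost (adjusted p = 0.0566 for both). Over the list alone, edgeR called Slc18a3, the vesicular acetylcholine transporter gene, and none of the other 3 lists' members, 2 of which had an unadjusted p under 0.05, 1 in the choroid plexus list and 1 among neuropeptides.

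In replicate 3, edgeR called 0 genes, with 1058 at an unadjusted p under 0.05. DESeq2 called 88, edgeR with no filter 86, and edgeR without replicates 1, 2 and 4 called 33, 27 and 1. Granule cell markers were higher (8 of 8 members, median log2 change 1.18, camera adjusted p = 0.0061), as were Purkinje cell markers (9 of 10, 0.84, adjusted p = 0.0170). With an estimated correlation both calls were lost (adjusted p = 0.851), and the call on Purkinje cell markers in replicate 3 was also lost without replicate 1 (adjusted p = 0.0742). Itpr1 stood at 1738 CPM against 417 to 796 CPM in the others, Car8 at 621 against 84.6 to 294 CPM, Cbln3 at 444 against 167 to 236 CPM and Fat2 at 266 against 73.0 to 105 CPM. Single genes were then tested within these lists, which the same comparison had called, so their calls are no separate support. Over the list alone, edgeR called 5 of 8 granule cell genes (Cbln3, Fat2, Gabra6, Neurod1 and Neurod2) and 2 of 10 Purkinje cell genes (Car8 and Itpr1). Other cell types' markers had median log2 changes of 0.99 for astrocytes, 1.09 for microglia and 0.72 for oligodendrocytes, none past the threshold (adjusted p = 0.0516 for each), and with the length trend removed those of astrocytes and microglia passed (adjusted p = 0.0456 for both). Gad2 and Slc32a1 stood at 239 and 29.3 CPM against 57.1 to 114 and 1.18 to 13.8 CPM in the others.

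In replicate 4, whose library number lies apart from the rest, 6 genes were higher and 1 lower (edgeR adjusted p = 0.0422 for each), and 2222 of 15083 genes had an unadjusted p under 0.05 (14.7%), the most of any library. Changes ran with transcript length here too (Spearman's rho 0.25 across genes). Cdr1 stood at 2026 CPM against 388 to 616 CPM (log2 fold change 2.14, SE 0.27), AK140265 at 1395 against 333 to 500 CPM (1.99, SE 0.27) and DQ539915 at 259 against 57.3 to 78.3 CPM (2.15, SE 0.31). The exons of Cdr1 (chromosome X, 61184005 to 61185558, minus strand) lie wholly within those of C230004F18Rik on the opposite strand, so its reads cannot be assigned without strand. Sema5a, a semaphorin of axon guidance (chromosome 15, 32244810 to 32696341), stood at 521 against 135 to 184 CPM (1.92, SE 0.28). Hspg2, which encodes the basement membrane proteoglycan perlecan (chromosome 4, 137468769 to 137570630), stood at 58.3 against 1.84 to 5.72 CPM (4.06, SE 0.58). Gm20110 had 222 counts in replicate 4 and 0 in each other library, at least 64.8-fold higher against a floor of 3 counts per library. Smim7 (chromosome 8, 72565188 to 72571088) was lower, at 7.64 against 67.0 to 105 CPM (-3.37, SE 0.49). These 7 genes were called under every alternative run, among larger totals of 416 with no filter, 384 with DESeq2, and 125, 74 and 82 without replicates 1, 2 and 3. Camera called 0 of 31 lists in replicate 4, with 5 lists at an unadjusted p under 0.05. With an estimated correlation and with fry it also called 0, and without replicate 2 or replicate 3, or with the length trend removed, it called 2 lists.

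Among the 320 tested genes of the lists fixed before the data were examined, edgeR called 0 in each library when adjusted over all genes. Adjusted over the list alone, 0 were called in replicate 1 (27 at an unadjusted p under 0.05), 0 in replicate 2 (7 at an unadjusted p under 0.05), 1 in replicate 3 (Gabrd) and 5 in replicate 4 (Ddx3y, Kdm5d, Nefm, Syn1 and Xist). With DESeq2 these counts were 0, 1, 12 and 28.

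Genes of the sex chromosomes differed between libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 629, 157 and 673 counts in replicates 1 to 3, or 65.4, 15.2 and 64.5 CPM, and 0 counts in replicate 4. Against a floor of 3 counts for the sum, replicate 4 was at least 239-, 55.8- and 236-fold lower than replicates 1, 2 and 3. Xist, the RNA that silences the X chromosome in females, stood at 19.3, 32.9, 31.6 and 111 CPM in replicates 1 to 4. Tsix had no count in any library. The labels used here do not give the sex of the mice.

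**Figure D4:**
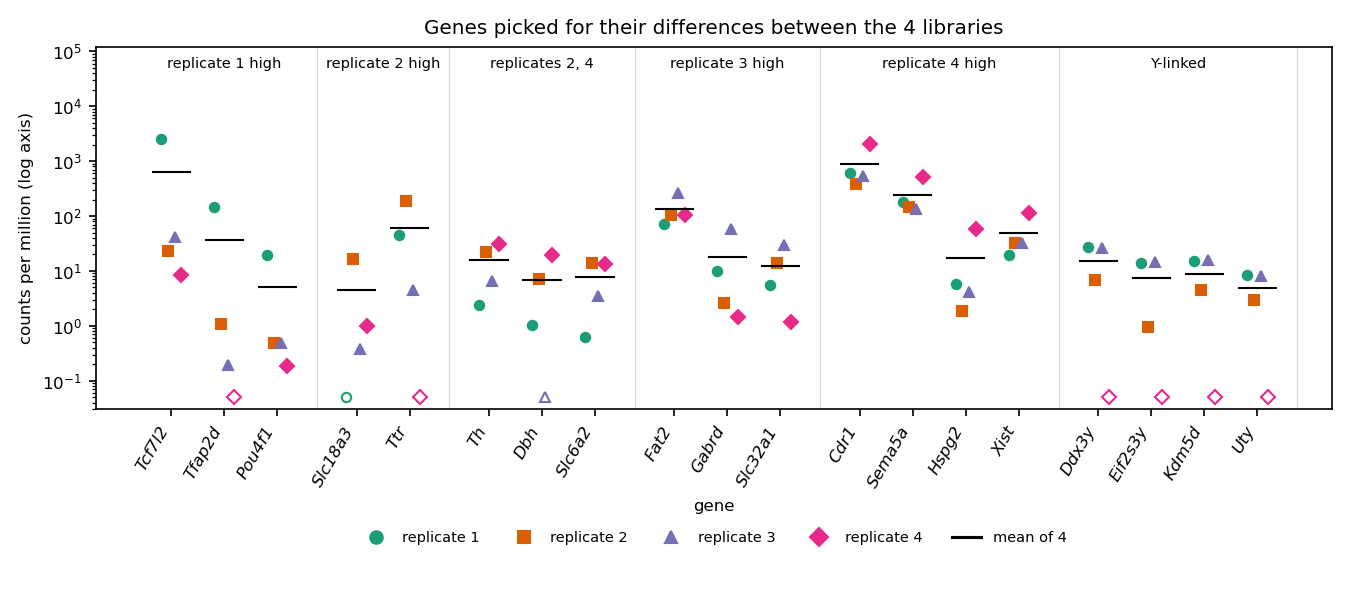
CPM on a log axis for genes picked after their levels were seen, with 1 point per library and a line at the mean of 4; open symbols at the bottom mark a count of 0. Tcf7l2 stands at 2486 CPM in replicate 1, Ttr at 190 CPM in replicate 2 and Cdr1 at 2026 CPM in replicate 4, and the 4 Y-linked genes have no count in replicate 4.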

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

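The tests of amplification noise in replicate 1, and all of those on replicate 3, were chosen after the values had been seen, as was the test on male mice in replicate 4. The comparison with each library's own share of highest genes was added after the results were seen, and so was the widening of the test on a lower share of tagged cells from 8 to 11 lists. Of 250 values tested, 32 had 1 library far from the other 3 (12.8%), 9 in replicate 1, 2 in replicate 2, 9 in replicate 3 and 12 in replicate 4. Some of the genes tested were chosen for their dispersion or a call in 1 library, and a gene with counts in only 1 library always stands apart, so this share cannot be set against chance. Of 219 genes not so chosen and above 3 counts in a library, 18 stood apart (8.22%). All values below are in CPM.

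In replicate 1, Tcf7l2 stood at 2486 against 8.55 to 42.0 and Tfap2d at 146 against 0 to 1.07. The vascular transporter gene Slco1a4 stood at 43.0 against 4.27 to 7.74 and the glycine receptor gene Glra4 at 20.4 against 0.57 to 2.46. Lower counts stood apart for Tgm6 at 3.64 against 0, Hoxa3 at 3.22 against 0 to 0.19 and Egr2 at 1.56 against 0 to 0.097. Trh stood at 0.104, a single count, against 0, which lies under the floor.

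Tcf7l2 and Tfap2d in replicate 1 may come from midbrain or thalamic neurons taken with the tissue, a hypothesis. Of 8 measured markers of those regions, 5 were highest in replicate 1 (Barhl2, Rgs16, Amotl1, Pou4f1 at 51.1 times the others, interval 28.6 to 101, and Synpo2 at 8.73 against up to 8.54), with a one-sided exact binomial p = 0.0273 against a chance of 25%. That criterion, written before the counts of these markers were seen, was too lenient, because 33.9% of 13656 genes are highest in replicate 1. Against that share the exact binomial p = 0.0943. The interval for Pou4f1 covers counting error only. The test counts only which library is highest, so Pou4f1 and Synpo2 weigh alike whatever the size of their differences. With 8 markers that may vary together, it cannot decide on this source, and no conclusion is drawn from it. Amplification noise of a kind found in every library was not decided either. In replicates 2 to 4, 0 genes reached 100 CPM and 20 times the other 3 libraries, but 3, 0, 1 and 1 genes in replicates 1 to 4 did so at 20 CPM. Other explanations for replicate 1 were not tested.

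In replicate 2, Tph2 stood at 0.194, under the floor, against 0.

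In replicate 3, Fat2 stood at 266 against 73.0 to 105, Slc1a1 at 158 against 119 to 123, Gabrd at 58.2 against 1.46 to 10.1 and Grin2c at 24.4 against 8.93 to 10.8. The perineuronal net gene Bcan stood at 45.0 against 22.3 to 26.0 and Tfap2b at 37.9 against 25.8 to 27.5. Among genes of large dispersion, Usb1 stood at 45.3 against 2.73 to 4.95, Trim25 at 40.1 against 1.27 to 5.63 and Gm340 at 36.3 against 1.64 to 5.92.

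Markers of Purkinje and granule cells were high in replicate 3, which may reflect RNA of these cortical neurons, a hypothesis found and tested on the same data. Of 18 markers, 15 were highest there, all but Pcp2, Gng13 and Slc17a7, but these are the genes that showed the pattern and markers of 1 cell type vary together. With an estimated correlation both lists lost their call (camera adjusted p = 0.851), so this source cannot be told apart from a difference between libraries by chance. Library scaling was not decided by the criterion set. The median log2 change of these markers, 1.01 (median absolute deviation 0.46), exceeded that of pan-neuronal genes, 0.01 (0.58), by 1.002, within the sum of both deviations (1.035). The median of these markers stayed at 1.02 (0.46) with DESeq2 size factors and at 1.09 (0.44) with Slc17a6 set equal between libraries. The median of these markers thus depended little on which of these scalings was used. TMM and DESeq2 factors gave almost the same median, and the other setting rests on a single gene. No further conclusion on scaling is drawn. A lower share of tagged cells that raises all other types alike was not decided. Medians of 11 lists ran from -1.26 (2.72) for choroid plexus and ependyma to 1.71 (1.21) for inhibitory nuclear neurons (permutation p = 0.0047). Between them lay -0.03 (0.31) for molecular layer interneurons and Golgi cells and 1.18 (0.39) for granule cells. Over the first 8 lists, permutation p = 0.138, and the lists added to those include both ends of the range. The permutation takes genes as independent, and markers also made by tagged cells would rise less. Other explanations for replicate 3 were not tested.

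In replicate 4, Nefm stood at 2502 against 897 to 1065, Nefh at 368 against 199 to 221, Cdr1 at 2026 against 388 to 616, AK140265 at 1395 against 333 to 500 and DQ539915 at 259 against 57.3 to 78.3. Sema5a stood at 521 against 135 to 184, Hspg2 at 58.3 against 1.84 to 5.72, Grin2a at 27.9 against 11 to 13.8 and Xist at 111 against 19.3 to 32.9. The oligodendrocyte lineage genes Gpr17 and Opalin stood at 5.19 against 0.104 to 0.77 and 3.46 against 0 to 0.38.

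The 4 Y-linked genes had a summed count of 0 in replicate 4, and 629, 157 and 673 in replicates 1 to 3. Chance loss of transcripts is argued against: of other genes with like counts in replicates 1 to 3, between 0.042 and 1.05% had no count in replicate 4, and the product of the 4 shares is 4.7e-11. The counts are consistent with no male mouse among those pooled for replicate 4, where Xist was also highest. The sex of the mice is not in the labels, so this stays a hypothesis, and other differences of replicate 4 cannot be assigned to sex or to its library number. No other explanation was tested.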

How the results depend on the processing

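Settings with length, totals without Rn45s, the lists of replicates 1 to 3 and a 2-fold minimum for pairs were chosen after seeing the data. Cell type lists lower than the reference numbered 9 to 11 under all alternatives (10 in the main analysis), and called pairs 33 to 39 except for 0 by the exact sign-flip test, which cannot pass with 4 libraries. The number of genes detected ranged from 8707 to 11962. Of the levels of named genes, 121 counted as moved and 121 as the same per union exon length, and 15 counted as moved with totals without Rn45s. Rankings of genes by CPM may therefore differ per exon length. Genes apart in replicate 1 numbered 32 with no filter and 26 with DESeq2, and from 7 to 31 with 1 other library left out. For replicate 2 these were 7 with DESeq2 and 0 to 2 with a library left out. For replicate 3 they were 86 with no filter, 88 with DESeq2 and 1 to 33 with a library left out. For replicate 4 they were 416 with no filter, 384 with DESeq2 and 74 to 125 with a library left out. DESeq2 called 12 genes higher and 14 lower in replicate 1, 1 and 6 in replicate 2, 23 and 65 in replicate 3, and 143 and 241 in replicate 4. Lists apart in replicates 1, 2 and 3 fell to 0 with an estimated correlation and 0 with fry. With the length trend removed, lists apart rose to 6 in replicate 3 and 2 in replicate 4. With a library left out they ranged from 4 to 9 in replicate 1, 3 to 5 in replicate 2, 2 to 10 in replicate 3 and 0 to 2 in replicate 4. Apart from the smaller number of samples in the last, the cause was not tested.

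Signs of log2 values turned as follows. Settings with length divide each count by its gene's length, which shifts a pair's ratio in every library by about the log2 ratio of the lengths. For the other settings the cause was not tested. Per union exon length, the ratio Gria2/Gria4 was -0.56, the ratio Grin2a/Grin2c -1.39, the ratio Kcna1/Kcna2 0.46 and the level of Purkinje cell markers against the reference list 0.0495. Per longest transcript, these ratios were -0.20, -1.14 and 0.67, and the ratio Chrm2/Chrm3 was -0.36. Without Slc17a6 in the reference, the Purkinje list was at 0.49. With 1 library left out, the Purkinje list ranged from -0.35 to 0.24, the ratio Tbr1/Eomes from -0.55 to 0.0703, the ratio Grin2a/Grin2c from -0.0680 to 0.81, the ratio Grin2a/Grin2d from -0.43 to 0.35 and the ratio Chrm2/Chrm3 from -0.19 to 0.30. The denominator without mitochondrially encoded genes was not run, since none was measured. No paired analysis was possible because the samples form 1 group. Depth limits genes under about 0.3 CPM.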

Other observations

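Families outside the fixed lists, chosen after the data had been seen, were summed, and each took at most 1.03% of all counts of named genes. The 6 genes of 14-3-3 proteins, adaptors of phosphorylated proteins, summed to 10306 ± 1717 CPM (SD, n = 4), with Ywhaz at 3299 ± 882, Ywhag at 2324 ± 453 and Ywhae at 2122 ± 341 CPM. Kinesin motor genes summed to 5864 ± 895 CPM, led by Kif1a at 1668 ± 400, Kif1b at 1134 ± 372 and Kif5a at 720 ± 117 CPM. Subunits of the vacuolar proton pump, which acidifies vesicles, summed to 4688 ± 595 CPM, with Atp6v1g2 alone at 1847 ± 761 CPM. Synaptotagmin genes summed to 2478 ± 138 CPM, led by Syt11 at 630 ± 64.9 CPM, and semaphorin genes to 1025 ± 216 CPM, led by Sema5a at 246 ± 184 and Sema6d at 230 ± 103 CPM.

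Genes of cytosolic ribosomal proteins summed to 10438, 6832, 6035 and 4255 CPM in replicates 1 to 4, with Rpl4 at 460 ± 107 and Rps15a at 353 ± 62.0 CPM. Complex I genes summed to 3777, 2578, 2608 and 1694 CPM and cytochrome c oxidase genes to 2301, 1614, 1387 and 1114 CPM. In the 25% of genes with the shortest exons the median log2 change of a library from the mean of the other 3 was 0.20 in replicate 1 and -0.23 in replicate 4, and in the 25% with the longest -0.20 and 0.27. Spearman's rho of change with length, across genes, was -0.27, -0.15, 0.04 and 0.25 in replicates 1 to 4, and genes are not independent replicates.

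Some genes of noradrenergic neurons were higher in replicates 2 and 4, and others of that list were not, with no test run on it. Th stood at 22.2 and 31.6 CPM there against 2.39 and 6.52 CPM in replicates 1 and 3, Slc6a2, the noradrenaline transporter gene, at 14 and 13.1 against 0.62 and 3.45 CPM, and Dbh at 7.28 and 19.1 against 1.04 and 0 CPM. Maoa stood at 40.1, 24.3, 29.8 and 32.8 CPM in replicates 1 to 4, Ddc at 2.18, 7.96, 0.479 and 2.82, and Gal at 0.728, 2.23, 0.383 and 0 CPM. Nps, the neuropeptide S gene, stood at 30.8 and 36.9 against 2.70 and 1.15 CPM. Cholinergic genes were highest in replicate 2, with Slc18a3 at 16.5 CPM against 0, 0.38 and 1 CPM in replicates 1, 3 and 4, and Chat at 10.3 against 0, 1.72 and 4 CPM. Tox3 stood at 86.8, 19.1, 1.05 and 5.73 CPM in replicates 1 to 4. Rn45s and Lars2 were both higher in replicates 2 and 3, Lars2 at 9594 and 7277 CPM against 4100 and 4794 CPM in replicates 1 and 4.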
